A study of Mus musculus with 6 samples.

How the data were processed

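The samples were RNA of MEF lines on 6 single-channel arrays, and each array's group was taken from its title: Ink4a/Arf-null with floxed Ezh2 (2 arrays), Ink4a/Arf-null with Ezh2 deleted (2), Ink4a/Arf wild-type with floxed Ezh2 (1) and Ink4a/Arf wild-type with Ezh2 deleted (1). Per the labels' protocols, cells were grown with serum and leukemia inhibitory factor and collected while growing exponentially. Total RNA was cleaned on columns, amplified with the Ambion WT Expression kit and biotin-labelled with the Affymetrix WT terminal labelling kit, also per the labels' protocols. The series design text mentions a transient transfection with esiRNA, which the titles do not. Nothing says that replicates came from separate cultures, so p-values of single probe sets measure the spread between these arrays, which may be technical.

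The authors deposited 3 tables: log2 expression values of the 6 arrays for 23346 probe sets, and a fold change table for each background. The scale is log2 per the file headers of the fold change tables, whose values per array equal those of the first table. The submitters' processing notes name limma without a version. Background correction, normalization, summarization, the array's full name, and the annotation and genome build were not given in the sources used here, so no coordinates are printed. In the deposited tables the log2 fold change was Ezh2-null minus fx/fx, and it matched the differences recomputed here within a tolerance of 1e-06. The deposited p-value columns were not adjusted, per the file headers. Those of the Ink4a/Arf-null table correlated with the limma p computed here at 0.9994 (log p, across probe sets). Those of the wild-type table, in which 23001 of 23346 lie under 0.05, come from 1 array against 1 and were not used. Gene symbols were taken from the Ink4a/Arf-null table, because 26 symbols differ in the other, where gene names had turned into dates. Of 20723 symbols, 1583 had more than 1 probe set.

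The values of the 4 Ink4a/Arf-null arrays and of the 2 wild-type arrays have different medians and spreads, as sets normalized apart would have. The Ink4a/Arf effect in Ezh2 fx/fx and in Ezh2-null MEFs was planned and was not tested for that reason: it would be a comparison across sets. Each Ezh2 comparison lies within a set.

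Tests used the deposited log2 values without further normalization or filter in limma 3.58.1 (with statmod 1.5.0) under R 4.3.3. A model with 1 mean per group (lmFit, eBayes) has 2 residual degrees of freedom, both from the Ink4a/Arf-null replicates. It gave the Ezh2 effect in that background, the Ezh2 effect in the wild-type pair and their difference. The last 2 borrow the spread of the Ink4a/Arf-null arrays and assume that each lone array varies as they do. An additive model of background and Ezh2 genotype, with 3 residual degrees of freedom, gave the averaged effect of 3 against 3 arrays and assumes the same log2 effect in both backgrounds. Tests were two-sided, and p was adjusted with the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. SE is the moderated standard error of limma.

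The 28 gene lists, the tests, the naming rule and most alternatives were fixed before the data were examined. They cover PRC2, PRC1, Hox genes, developmental transcription factors, DNA replication, mitosis, G1 cyclins and pocket proteins, CDK inhibitors, p53 targets, DNA damage and repair, interferon-stimulated genes, secreted factors of inflammation and senescence, fibroblast matrix, contractile, skeletal muscle, imprinted, germline, neural, bone and cartilage, adipocyte, cholesterol, amino acid response, hypoxia and glycolysis, and ribosomal protein genes, and markers of macrophages, endothelium, epithelium and pluripotent cells. Of 915 list entries 907 were matched, 9 of them through an older symbol in the RefSeq gene table of the mouse assembly GRCm38.p6. Each gene was represented by its probe set with the highest mean. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, and again with the correlation estimated from the residuals. The latter version takes its p on the residual degrees of freedom of the fit (2, or 3 for the additive model). It therefore has little power, and a lost call need not come from correlation between genes. At the preset correlation camera draws its p from genes against genes, not from the spread between arrays. Limma's fry, which tests a list's own genes for a shared direction, was planned beside it for the null set and the averaged effect. Camera compares a list with all other genes, whose median difference lies slightly below 0 in the Ink4a/Arf-null set, so for lists with medians near 0 that were not called (such as PRC1, neural and ribosomal protein genes) its direction can differ from the sign of the median. Counts adjusted over the list alone use the p of the list's members only. In the wild-type pair each list's median was placed among 10000 random lists matched in 20 expression bins.

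The text names Ezh2, Cdkn2a and Cdkn2b first, then for each comparison up to 10 genes each way with the largest log2 difference among those that passed and whose arrays do not overlap between groups (5 each way for the difference between backgrounds), filled up with the largest differences at an unadjusted p under 0.05 where fewer passed. For the averaged effect the sign had to be the same in both backgrounds. Gene models without a proper name, receptors of smell and small RNAs were left out. Up to 4 members per list were named by the size of the moderated statistic per comparison. A gene with several probe sets was given by the one with the highest mean. Some genes that the rule picks are not reported here.

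The replicate numbers of the Ink4a/Arf-null groups share only a number, and the fit with them as a block is an alternative. Other alternatives were median centring, quantile normalization of all arrays, filters at the median or the lower quartile of signal, an intensity trend with robust moderation, other thresholds, 1 probe set per gene, the mean of a gene's probe sets, leaving out each array, the 4 Ink4a/Arf-null arrays alone, and, added after the data were seen, a wider spread of the wild-type arrays.

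The fits were tested on simulated data of 23346 probe sets with changes planted in 50 probe sets per size. In the Ink4a/Arf-null comparison 14% of changes of 0.5 (log2), 88% of changes of 1 and 100% of changes of 2 were recovered, with 4 false calls. The averaged effect recovered 56%, 94% and 100% with 7 false calls, and the wild-type pair 2%, 58% and 98% with 9. All 6 simulated arrays were given the same spread. The wild-type values therefore assume, and do not test, that lone arrays vary as the replicates do. A list shifted by 0.2 (log2) was called and none of 27 others was, in simulations with independent genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.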

Results

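Gene expression was measured in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, of a strain labelled Ola129. The cells differed at Ezh2, the catalytic subunit of the Polycomb repressive complex PRC2, which places the repressive methyl mark on histone H3. They also differed at Ink4a/Arf (Cdkn2a), the tumour suppressor locus whose products restrain the cell cycle and stabilise p53. Total RNA of 6 samples was hybridised to 6 whole-transcript arrays. In the Ink4a/Arf-null background there were 2 arrays with floxed Ezh2 alleles (fx/fx) and 2 Ezh2-null arrays, and in the Ink4a/Arf wild-type background 1 array of each Ezh2 genotype. The series title links Polycomb proteins to proliferation and DNA replication. Its design text speaks of a transient knockdown of Ezh2, whereas the sample titles name alleles. The groups here follow the titles, so "Ezh2-null" means labelled so.

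Each array gave log2 values for 23346 probe sets of 20723 gene symbols. The array medians lay between 8.25 and 8.32 in the Ink4a/Arf-null background and at 7.5 and 7.51 in the wild-type background, with different spreads (SD 2.18 to 2.24 against 2.42 and 2.43). The sets therefore look normalized apart from each other, and log2 levels are compared only within a background. Ranks within an array are set side by side across backgrounds for the Hox genes only. The Ezh2 fx/fx replicate 1 array of the Ink4a/Arf-null background stood apart from its 3 companions: the first principal component of these 4 arrays, with 50.1% of the variance, separated it from the rest. It differed from fx/fx replicate 2 by a root mean square of 0.210 (log2), against 0.14 between the Ezh2-null replicates. Each fx/fx array of this background lay closer to the Ezh2-null arrays (0.161 to 0.206) than to the other fx/fx array. The number of arrays limits the precision of every value.

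Ezh2 itself (probe set 10544501) had log2 values of 10.92 and 10.91 on the Ink4a/Arf-null fx/fx arrays and 10.62 and 10.51 on the Ezh2-null arrays. In the wild-type background it read 10.48 with floxed Ezh2 and 10.12 without. The difference was -0.35 (SE 0.08, 2 against 2 arrays; limma adjusted p = 0.58) and -0.36 in the wild-type pair, or 0.78-fold in each. All 3 Ezh2-null arrays thus read below the fx/fx arrays of their background, but the difference did not pass the test. It passed with an intensity trend in the variance (adjusted p = 0.038 in the null set, 0.026 in the wild-type pair) and, in the wild-type pair, when only probe sets above the median signal were tested (0.044). In the wild-type pair the fall was like the median of the replication genes (-0.37, against -0.17 in the null set), so its size there is not particular to Ezh2. Where the probes of this set lie relative to the deleted part was not given in the sources used here. The signal therefore checks the labels at most in part. Cdkn2a (probe set 10514340) read 8.29 and 8.18 against 8.11 and 8.20 in the Ink4a/Arf-null background, where the same limit applies, and 7.91 with and 8.62 without intact Ezh2 in the wild-type background. Its neighbour Cdkn2b (probe set 10514347), which encodes the CDK inhibitor p15, read 11.37 and 11.37 against 11.58 and 11.45, and 8.69 against 9.31 in the wild-type pair.

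**Figure D1:**
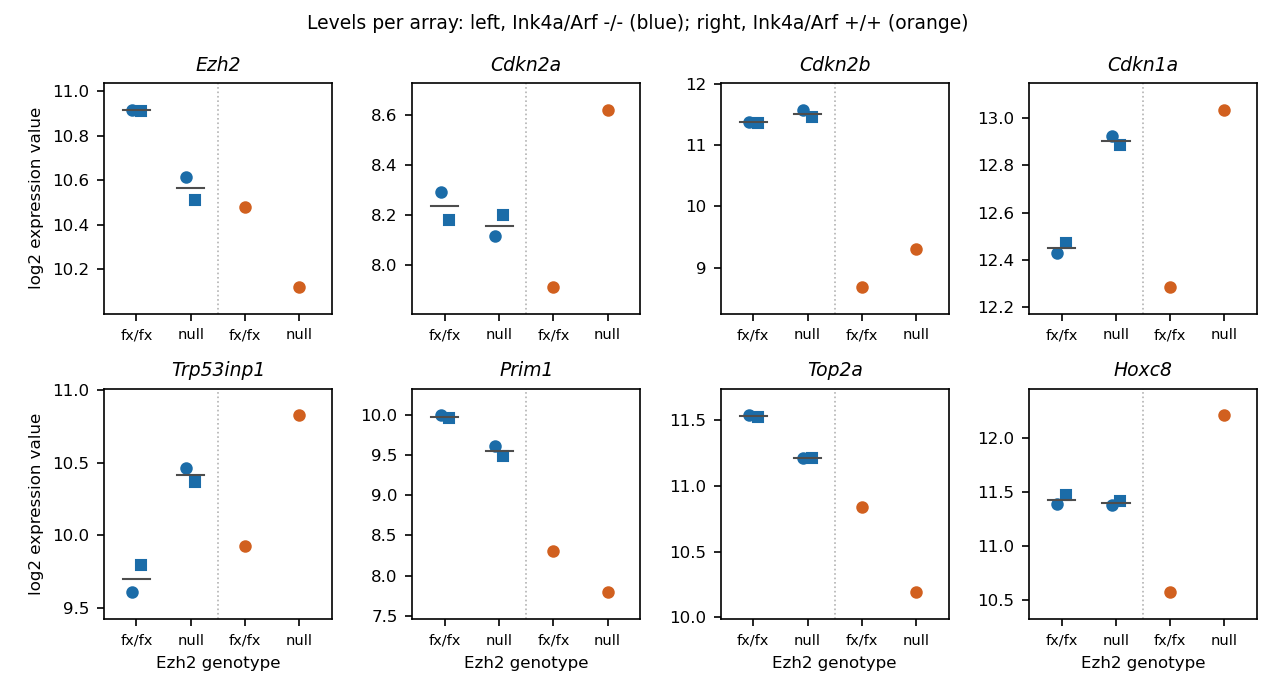
Log2 expression values (y axis) of 8 genes on each of the 6 arrays, by Ezh2 genotype (x axis); circles and squares are replicates 1 and 2 of the Ink4a/Arf-null background, lines their means, and the right side of each panel holds the 2 wild-type arrays. Ezh2 reads lower on each Ezh2-null array than on the fx/fx arrays of its background (10.62 and 10.51 against 10.92 and 10.91), and Hoxc8 reads 10.57 and 12.21 in the wild-type pair.

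In Ink4a/Arf-null MEFs, where the question is what loss of Ezh2 does without the Ink4a/Arf barrier, the Ezh2-null arrays had lower values for genes of DNA replication, mitosis and DNA repair, and higher values for p53 target genes and several secreted and matrix genes. These shifts were small for single genes. Of 60 replication origin and fork genes, 59 had a negative difference, with a median of -0.17 (log2). The primase subunit Prim1 differed by -0.42 (SE 0.08), the origin recognition subunit Orc1 by -0.35 (SE 0.07) and the fork protection gene Tipin by -0.38 (SE 0.07), each from 2 against 2 arrays. All 44 mitotic genes were lower, with a median of -0.18, among them the topoisomerase Top2a at -0.32 (SE 0.07) and the kinesin Kif18a at -0.28 (SE 0.07). All 37 genes of the damage checkpoint and repair list were lower too, with a median of -0.18, with the checkpoint kinase Chek1 at -0.21 (SE 0.08). No member of these 3 lists passed over all probe sets or adjusted over the list alone. As lists they were called lower by limma's camera with adjusted p of 2.1e-17 for replication, 2.5e-16 for mitosis and 1.3e-12 for repair. Such values compare genes with genes and do not measure the spread between arrays. With an estimated correlation between genes the adjusted p was 0.26, 0.18 and 0.26, and none was called. For mitosis the estimate, 0.006, lay below the preset 0.01, so correlation between genes did not end that call. Fry gave these 3 lists an adjusted p of 0.091, 0.033 and 0.10, and called mitosis alone among them.

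Among 35 p53 target genes 26 had a positive difference, with a median of 0.10. Adjusted over the list alone 6 of them rose, and over all probe sets none did. Members with higher values included Trp53inp1, a cofactor of p53 in apoptosis, at 0.71 (SE 0.09), Psrc1 at 0.68 (SE 0.07), the receptor Eda2r at 0.67 (SE 0.08), and the CDK inhibitor Cdkn1a (p21) at 0.45 (SE 0.07). Camera called the list higher with adjusted p = 1.4e-12, against adjusted p = 0.18 with an estimated correlation. That estimate, 0.008, also lay below the preset 0.01. The inflammatory and senescence-associated secreted factors were called higher (median 0.08, adjusted p = 6.6e-10), with Cxcl10 at 0.78 (SE 0.07) and Igfbp5 at 0.58 (SE 0.08), and 5 of 40 rose adjusted over the list alone. Fibroblast matrix genes (median 0.07, adjusted p = 1.2e-08), with elastin (Eln) at 0.53 and decorin (Dcn) at 0.43, and imprinted genes (median 0.07, adjusted p = 5.7e-07), with Peg3 at 0.47, were called higher as well, each with 1 gene that rose adjusted over the list alone. Decorin belongs to both lists. Interferon-stimulated genes were called higher (median 0.05, adjusted p = 8.4e-05), with 2 of 40 that rose adjusted over the list alone, and so were contractile genes of smooth muscle (median 0.02, adjusted p = 0.023). Cholesterol biosynthesis genes (median -0.07, adjusted p = 0.028) and Hox genes (median -0.07, adjusted p = 0.039) were called lower. For these 7 lists the adjusted p with an estimated correlation was 0.54, 0.18, 0.18, 0.71, 0.75, 0.81 and 0.83, in the order given. Fry called only the imprinted list among them (adjusted p = 0.033), and it did not call the p53 targets (0.10). The calls of the Hox, contractile and cholesterol lists were also lost without the Ezh2-null replicate 2 array (adjusted p = 0.33 for each), those of the Hox and cholesterol lists without fx/fx replicate 2 (0.20 for each), and that of the contractile list without fx/fx replicate 1 (0.40) and with quantile normalization (0.12). Among probe sets above the median signal the Hox (0.057) and contractile lists (0.052) were not called either. Without fx/fx replicate 1, the array that stood apart, the median of the replication, mitosis and repair genes was -0.19 and 16 lists were called.

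The other 17 lists were not called in this background. They held PRC2 (median -0.04, Ezh2 included) and PRC1 subunits (-0.00), developmental transcription factors outside the Hox clusters (-0.04), cyclins and pocket proteins of G1 (-0.05), CDK inhibitors (0.05), amino acid response (-0.02), hypoxia and glycolysis (-0.03), ribosomal protein (-0.02), bone and cartilage (0.03), skeletal muscle (-0.04), germline (-0.04), neural (-0.01) and adipocyte genes (0.00), and markers of macrophages (0.03), endothelium (0.01), epithelium (-0.01) and pluripotent cells (-0.02). These small medians have no firm sign: those of the PRC1, neural and epithelial lists turned positive after median centring or quantile normalization, and those of the germline and pluripotency lists after quantile normalization. The lowest of their adjusted p was 0.105, for endothelial markers. Adjusted over the list alone, 2 bone and cartilage genes, 1 neural gene and 1 CDK inhibitor (Cdkn1a, also a p53 target) rose. The 1 PRC2 gene that fell was Ezh2 itself.

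No single probe set passed limma's test in this comparison (lowest adjusted p = 0.26), while 1617 had an unadjusted p under 0.05, 654 higher and 963 lower, where 1167 would come by chance. The authors' deposited p-values, which track those computed here, had 972 under 0.05 and also none that passed after adjustment. Among genes at an unadjusted p under 0.05 whose arrays did not overlap, the highest values were those of the costimulatory ligand Cd80 at 0.93 (SE 0.07), Fndc3c1 at 0.85 with a wider spread between replicates (SE 0.14), the chemokine Cxcl10 at 0.78, the protease inhibitor Serpine2 at 0.77 (SE 0.07), the fatty acid binding protein Fabp7 at 0.76 (SE 0.07), the chemokine Ccl17 at 0.75 (SE 0.08), Rgs4 at 0.74 (SE 0.08), Trp53inp1 at 0.71 and the cartilage collagen Col10a1 at 0.69 (SE 0.08). Lower values were those of Klra33 at -0.73 (SE 0.09), the nucleosome binding protein Hmgn5 at -0.68 (SE 0.14), Wfdc6a at -0.57 and the proliferation-associated gene Shcbp1 at -0.52 (SE 0.08). Other genes picked by the same rule were dim, and no detection value separates them from background, so their differences are not given. Cma2, Dleu2, Zfp600 and Defa26 read below the 10th percentile of signal (5.46 to 5.64) on all 4 arrays. Calr4 did so on both Ezh2-null arrays and Sprr2b on Ezh2-null replicate 2. The glutathione transferase Gsta1 (6.30 and 5.09 with floxed Ezh2, 3.73 and 3.63 without) did so on both Ezh2-null arrays and on fx/fx replicate 2. Gsta1 passed without fx/fx replicate 2, but then rested on fx/fx replicate 1 alone, the array that stood apart. An intensity trend in the variance called 98 probe sets, 79 higher and 19 lower, and a test of only the probe sets above the median signal called 19. Leaving out fx/fx replicate 2 called 13 and leaving out Ezh2-null replicate 2 called 5.

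In Ink4a/Arf wild-type MEFs the same comparison rests on 1 array per genotype and has no replicate check. Replication (median -0.37, 59 of 60 genes lower), mitosis (median -0.48, 42 of 44 lower) and repair genes (median -0.39, 35 of 37 lower) were again lower on the Ezh2-null array. Each median lay at percentile 0 of 10000 random lists matched on expression. The proliferation marker Mki67 differed by -0.96, Chek1 by -0.80 and Orc1 by -0.64. The p53 targets were higher (median 0.23, 29 of 35 genes), with Eda2r at 1.15, the death receptor Fas at 0.98, Trp53inp1 at 0.90 and Cdkn1a at 0.75. Bone and cartilage genes were higher (median 0.23, 23 of 30), such as alkaline phosphatase (Alpl) at 1.52 and Comp at 1.41, and cholesterol genes were lower (median -0.23, 23 of 24). PRC2 subunits were lower (median -0.23, 9 of 10 genes), with Ezh2 itself counted among them and Suz12 at -0.37. Other lists called higher in the null set did not stand out here. Secreted factors (median 0.05) lay at percentile 87.3 of the random lists, interferon-stimulated genes (0.06) at 86.9, imprinted genes (0.07) at 96.8, and matrix genes (0.02, or -0.00 after median centring, 22 higher and 20 lower) at 74.0. Contractile genes, called higher in the null set, were lower here (median -0.09, percentile 1.97). Ribosomal protein genes, not called in the null set, were slightly lower too (median -0.06, 37 of 46 lower, percentile 0.86).

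The Hox genes, which specify position along the body axis and are standard targets of PRC2, showed the highest list median in this pair. Of 39 Hox genes 37 were higher on the Ezh2-null array, with a median of 0.48, among them Hoxc8 (1.65), Hoxc10 (1.42) and Hoxb9 (1.24). In the Ink4a/Arf-null background 33 of the 39 had a negative difference. Median centring or quantile normalization of the arrays left the sign of the Hox medians as it was in both backgrounds (0.47 and 0.39 in the wild-type pair, -0.05 and -0.05 in the null set).

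**Figure D2:**
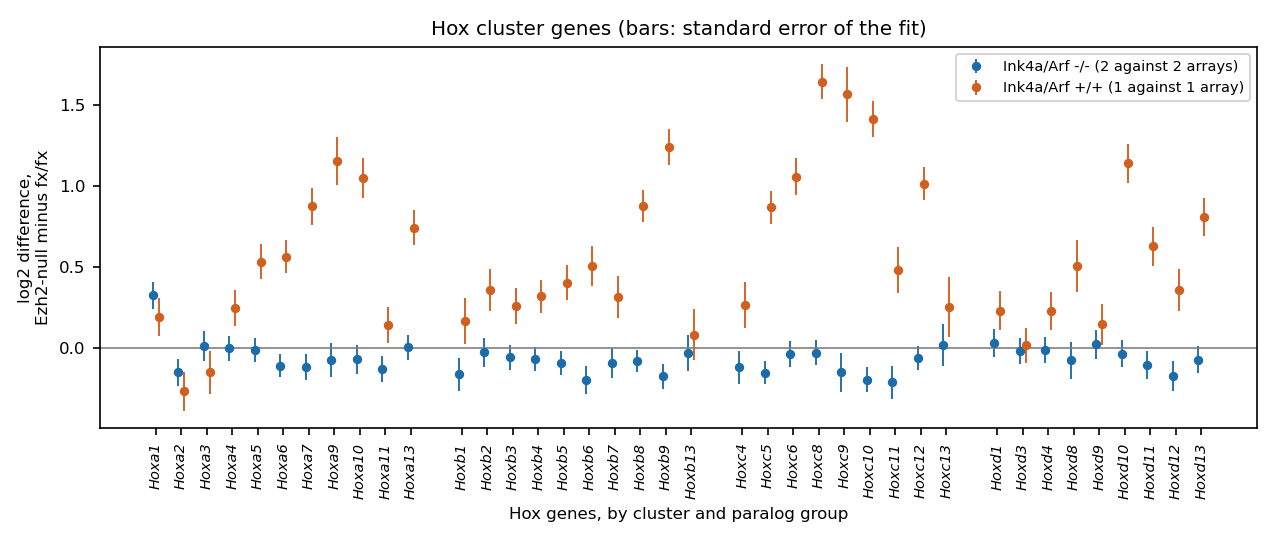
Log2 difference between Ezh2-null and Ezh2 fx/fx arrays (y axis) for 39 Hox genes in cluster order (x axis), in the Ink4a/Arf-null (2 against 2 arrays) and wild-type background (1 against 1); bars are standard errors of the limma fit, borrowed from the Ink4a/Arf-null arrays for the wild-type pair. The wild-type differences reach 1.65 at Hoxc8, while those of the null background have a median of -0.07.

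When the lone wild-type arrays were assumed to vary as the Ink4a/Arf-null replicates do, limma called 623 probe sets in the wild-type pair, 398 higher and 225 lower. The majority turned with an intensity trend in the variance (966 higher, 1086 lower) and above the median signal (664 higher, 864 lower). The highest, with each gene read by its brightest probe set, were the aldehyde dehydrogenases Aldh1a1 (3.03) and Aldh1a7 (2.61), the teneurin Odz1 (2.97), Rgs5 (2.36), Angptl1 (2.36), Fabp7 (2.27), the myelin protein Pmp2 (2.18), Slc22a23 (2.17), the protease Pappa2 (2.16) and the phosphatase Ptprq (2.15). Among the lowest were the heart transcription factor Tbx20 (-3.11), the chemokine Ppbp (-2.93), the serotonin receptor Htr1b (-2.23), Stmn2 (-1.96), dermatopontin (Dpt, -1.78), Lrrtm3 (-1.78), desmin (Des, -1.75), Adamts15 (-1.72) and the chemokine Cxcl5 (-1.72). Their SE lay between 0.10 and 0.23, and their adjusted p between 0.0016 and 0.014. Cdkn2a, at 0.71 (SE 0.12), passed with adjusted p = 0.043, Cdkn2b at 0.62 (SE 0.11) narrowly did not (adjusted p = 0.058), and 14 Hox genes passed over all probe sets, all higher. Cdkn2b passed with median centring (0.041), quantile normalization (0.038), 1 probe set per gene (0.045), the intensity trend (0.00094) and the filters at the median (0.0079) and lower quartile of signal (0.021), and without either fx/fx replicate of the null set (0.043). No call remained when the wild-type arrays were given 4 times the variance, an alternative added after the data were seen. The count was 1238 without either fx/fx replicate of the Ink4a/Arf-null set and 340 without either Ezh2-null replicate, where Cdkn2a no longer passed (adjusted p = 0.094).

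**Figure D3:**
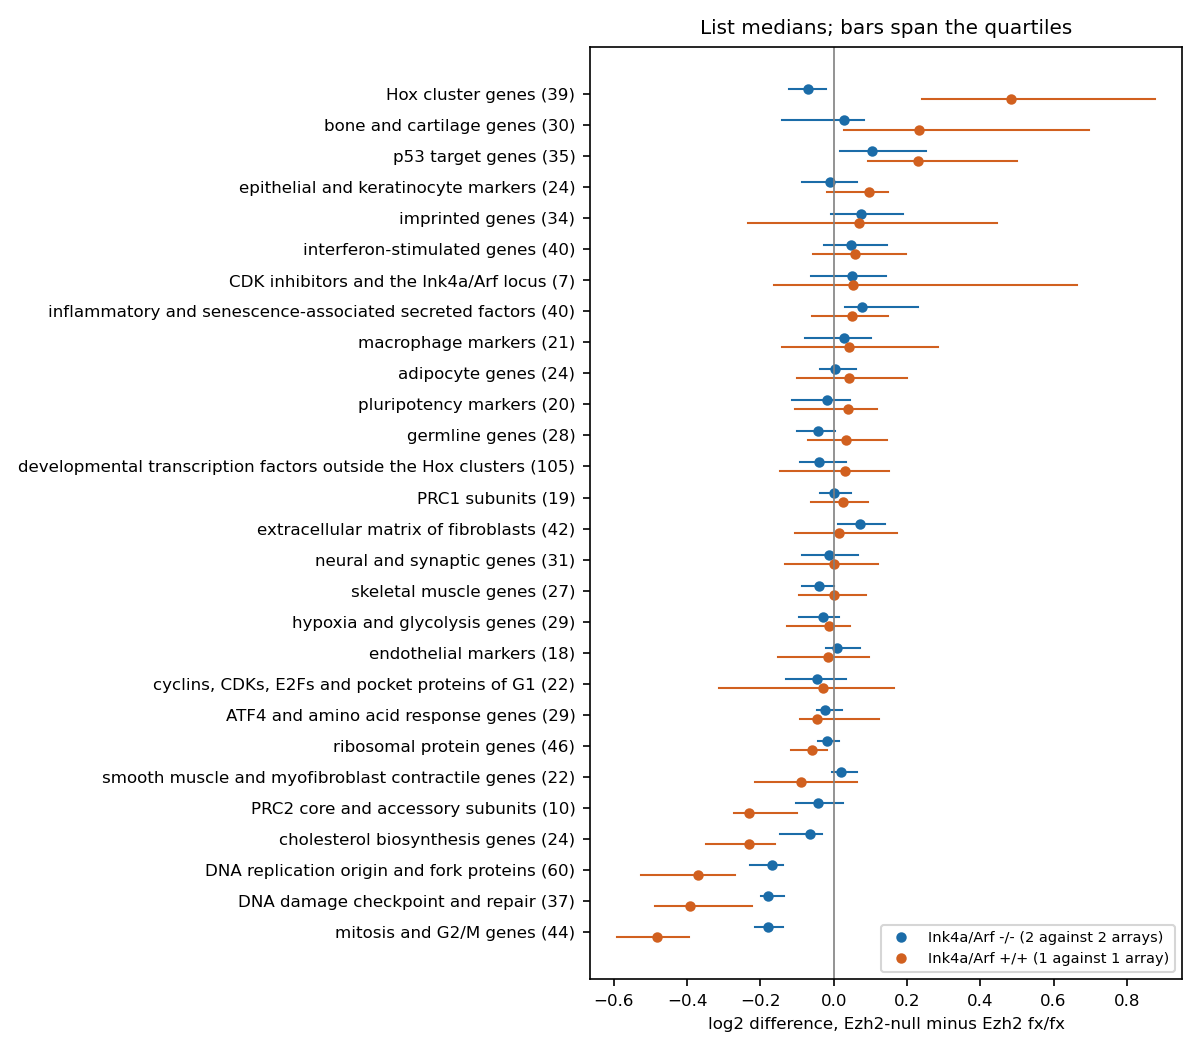
Median log2 difference between Ezh2-null and Ezh2 fx/fx arrays (x axis) of the 28 gene lists (y axis, genes measured in parentheses) in the Ink4a/Arf-null and wild-type background; bars span the quartiles of the members. Replication, repair and mitosis lists lie lowest in both backgrounds (medians -0.17 to -0.18 and -0.37 to -0.48), and the Hox list lies on opposite sides of 0.

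Averaged over both backgrounds, with 3 Ezh2-null against 3 fx/fx arrays, replication, mitosis and repair genes were lower and p53 targets higher. This average reuses the 4 Ink4a/Arf-null arrays and gives them more weight than the wild-type pair, so it is no independent check of them. Adjusted over the list alone 43 of 60 replication genes, 37 of 44 mitotic genes and 24 of 37 repair genes fell, and 14 of 35 p53 targets rose while 1 fell. Over all probe sets none passed limma's test (lowest adjusted p = 0.13), with 2476 at an unadjusted p under 0.05, 959 higher and 1517 lower. Camera called 11 lists, where the other splits of the 6 arrays into 3 and 3 called 7 to 11, with adjusted p of 1.0e-26 for replication, 2.3e-23 for mitosis, 3.9e-18 for repair and 4.6e-13 for p53 targets. With an estimated correlation, on the 3 residual degrees of freedom of this fit, these were 0.33, 0.44, 0.33 and 0.33. By fry only the imprinted list was called (adjusted p = 0.016). Also called were cholesterol genes as lower (1.2e-05), and secreted factors (3.3e-05), Hox (2.5e-04), imprinted (6.2e-04), interferon-stimulated (6.9e-04), matrix (1.1e-03) and bone and cartilage genes (1.3e-03) as higher, none with an estimated correlation (adjusted p of 0.57, 0.33, 0.77, 0.33, 0.44, 0.33 and 0.74 in that order). The Hox call comes from the wild-type pair, since the median of the null background was negative and the list was called lower there. Bone and cartilage genes were not called in the null set (adjusted p = 0.11), and the contractile list called there was not called in the average (0.92). Without fx/fx replicate 1 of the Ink4a/Arf-null set the matrix and imprinted lists were no longer called (adjusted p = 0.13 and 0.12), nor was the interferon-stimulated list among probe sets above the median signal (0.050, just over the threshold).

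Genes were ranked by averaged value among those with an unadjusted p under 0.05 and the same sign in both backgrounds, none of which passed. The highest of these were Fabp7 at 1.26 (SE 0.28), Rgs5 at 1.2 (SE 0.32), Cd80 at 1.09 (SE 0.11), Aldh1a7 at 1.08 (SE 0.42), Fndc3c1 at 1.05 (SE 0.16), Ccl17 at 1.03 (SE 0.16), Serpine2 at 1.01 (SE 0.14), Eln at 0.97 (SE 0.24), Pmp2 at 0.96 (SE 0.35) and Col10a1 at 0.95 (SE 0.15). The lowest under the same rule were Klra33 at -0.93 (SE 0.13), Lrrtm3 at -0.71 (SE 0.30), the replication-dependent histone gene Hist2h2ab at -0.70 (SE 0.15), Phxr4 at -0.63, Hmgn5 at -0.62, the growth factor receptor Pdgfra at -0.58, Syne2 at -0.56, the condensin subunit Ncapg at -0.54 (SE 0.13), Shcbp1 at -0.52 (SE 0.06) and Hmgb3 at -0.51. Ezh2 differed by -0.35 (SE 0.06, adjusted p = 0.27, or 0.047 with an intensity trend in the variance). With that trend 46 probe sets were called, 35 higher and 11 lower, with quantile normalization 8, all higher, and above the median signal 9.

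The comparisons in the 2 backgrounds share no array. Across probe sets, which are not independent replicates, their log2 differences correlated with r = 0.25 (Spearman's rho 0.25). Of the 654 probe sets higher at an unadjusted p under 0.05 in the Ink4a/Arf-null set 487 were also higher in the wild-type pair (74.5%, against 50.1% of all probe sets), and of the 963 lower ones 669 were also lower (69.5%, against 48.1%). No probe set was called in the Ink4a/Arf-null set, where the unadjusted p replaced the planned threshold. Of the 398 probe sets called higher in the wild-type pair with the borrowed spread 310 were higher in the null set (77.9%, against 39.1% of all probe sets), and of the 225 called lower 145 were lower (64.4%, against 60.9%). The correlation was 0.40 among probe sets above the median signal and 0.12 without fx/fx replicate 2.

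The difference of the Ezh2 effect between backgrounds was tested as an interaction, under the same assumption about the lone arrays. It passed for 95 probe sets, in 64 of which the wild-type pair had the more positive effect and in 31 the more negative. The count rose to 423 above the median signal, where the balance turned (200 more positive, 223 more negative), and to 738 with the intensity trend (385 and 353). Without fx/fx replicate 2 it was 245, and without Ezh2-null replicates 1 and 2 in turn 52 and 44. Aldh1a1 (3.05), Odz1 (2.97), Angptl1 (2.54), Aldh1a7 (2.29) and the zinc finger factor Zic5 (1.97) had more positive effects in the wild-type pair, and Ppbp (-3.39), Tbx20 (-3.0), Htr1b (-2.20), Des (-1.89) and Stmn2 (-1.83) more negative ones (adjusted p between 0.0058 and 0.047). Ppbp differed by 0.46 in the null set and by -2.93 in the wild-type pair. Camera, added for this contrast after the data were seen, called Hox genes (median difference 0.54, adjusted p = 2.2e-19), bone and cartilage genes (0.26, 4.2e-05) and p53 targets (0.12, 0.048) as more positive in the wild-type pair, and mitosis (-0.30, 5.7e-16), replication (-0.23, 8.8e-11), repair (-0.18, 8.7e-07), cholesterol (-0.16, 3.5e-05) and contractile genes (-0.06, 0.0019) as more negative. With an estimated correlation the adjusted p was 0.66 for Hox genes, 0.34 for mitosis and no list was called. Background and array set coincide here and cannot be told apart, and the count of 95 fell to 0 when the wild-type arrays were given 4 times the variance.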

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

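The tests of expression-dependent compression and of cycling cells below were chosen only after the result was seen, and so was the list test of the difference between backgrounds. The difference of the Ezh2 effect between backgrounds, tested as an interaction, passed for 95 probe sets. Named genes among them were Aldh1a1 (3.05), Odz1 (2.97), Angptl1 (2.54), Aldh1a7 (2.29), Zic5 (1.97), Ppbp (-3.39), Tbx20 (-3.0), Htr1b (-2.20), Des (-1.89) and Stmn2 (-1.83), as log2 differences of the wild-type pair minus the null set. Among lists, the median of this difference was 0.54 for Hox genes, 0.26 for bone and cartilage genes, 0.12 for p53 targets, -0.30 for mitosis, -0.23 for replication, -0.18 for repair, -0.16 for cholesterol and -0.060 for contractile genes. Without fx/fx replicate 2 the count was 245, without the Ezh2-null replicates 1 and 2 in turn 52 and 44, and 0 with a wider spread of the wild-type arrays.

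Hox genes were higher in the wild-type Ezh2-null array and not in the Ink4a/Arf-null arrays. After joint quantile normalization the median difference between backgrounds stayed at 0.52, beside 0.54 as deposited. The spreads of the sets differ, but only by a small part of their size (SD 2.18 to 2.24 against 2.42 and 2.43). The normalization could therefore hardly remove the difference, and this test of a different scale decides little. The values show something narrower: the medians had opposite signs (0.48 and -0.07), also after either rescaling, which a scale factor alone does not produce. A shift along the body axis between the wild-type cultures stays open. The 15 anterior genes had a median of 0.25 (13 higher), the 8 middle ones 0.72 and the 16 posterior ones 0.78 (all higher in both groups). A rise of anterior and posterior genes together met the bound set beforehand against such a shift, but that bound was wrong, as judged after the values were seen: anterior Hox genes stay expressed in posterior cells, and the rise was graded toward posterior genes. Hox genes that were already raised in the Ink4a/Arf-null cultures with floxed Ezh2 stay open too: their median rank within the array was the 54.7th and 55.0th percentile there, between 46.0 with and 55.3 without intact Ezh2 in the wild-type pair, and background and array set cannot be told apart. Loss of Polycomb repression that depends on the background is a candidate explanation, not tested beyond these values, on 1 array per genotype.

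Replication, mitosis and repair genes (141 in the 3 lists) were lower in the Ezh2-null arrays of both backgrounds, 135 of them in both, with medians of -0.18 and -0.42. Fx/fx replicate 1 alone is argued against, since without it the median was -0.19 and all 141 genes were lower. The pooled median lay at percentile 0 of random lists matched on expression in both backgrounds. Each of the 3 lists already did so, so this was no further test. It shows that genes of like expression did not fall as far. The lowest random median was -0.05 in the null set and -0.10 in the wild-type pair, which argues against compression by expression level as the whole cause. A lower share of cycling cells stays open. Replication and mitosis medians differed by 0.01 in the null set and 0.11 in the wild-type pair, but with null medians of -0.17 and -0.18 a gap over the bound of 0.15, set after these were seen, could hardly arise, so the test decides nothing. An effect of Ezh2 on these genes apart from the share of cycling cells was not tested.

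The Ink4a/Arf-null fx/fx replicate 1 array lay apart from its 3 companions. Its distance to them was 1.30 times their distance to each other as deposited and 1.17 times after quantile normalization, which lies between the bounds set beforehand, so a different signal distribution stays open. RNA of other cell types stays open too: of 8 marker lists the largest median deviation was 0.15 (log2), in macrophage markers, again between the bounds; their median rank over the Ink4a/Arf-null arrays lay at percentile 46.3. No biological explanation was tested, since the design names none within a group.

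The averaged effect compares 3 against 3 arrays, and 10 splits cannot give a share under 0.05. The genotype split gave 2476 probe sets at an unadjusted p under 0.05, the highest other split 1844, with 1 of the 10 splits, itself, giving as many. For lists called by camera with its preset correlation, the genotype split gave 11 and the other splits 7 to 11, the highest also 11, with 3 of the 10 splits, itself included, giving as many. A count of 11 thus lies near that of other groupings. The split with 1844 also had 6 probe sets past the adjusted threshold, where the genotype split had 0. It put both wild-type arrays with fx/fx replicate 1 of the Ink4a/Arf-null set. With background in the model it thus compared that array, which stood apart, with the other 3 Ink4a/Arf-null arrays. Some of the 10 splits, that one included, place both wild-type arrays on the same side, which the genotype split does not. The shares therefore mix groupings that are unlike in background.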

How the results depend on the processing

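Of these alternatives, the wider wild-type spread was chosen after the data were seen. The planned tests of the Ink4a/Arf effect in Ezh2 fx/fx and in Ezh2-null MEFs were not run under any setting, because the sets look normalized apart. Directions of the genes named by rank, and camera's direction for the lists called in the null set or averaged, held under every alternative run except on leaving out arrays: the difference between backgrounds of Ezh2 ranged from -0.062 to 0.044, the latter without Ezh2-null replicate 1, and the averaged Cdkn2a value from -0.078 to 0.29, the former without either wild-type array, since the null arrays alone then inform it. Other named list members were recomputed under both scalings and without each null array; of their printed differences that of Zic2 in the null set, -0.00, changed sign. In the wild-type pair, where camera was not run, the matrix list median, 0.02, became -0.00 after centring. Small medians of uncalled lists turned too: in the null set PRC1, neural and epithelial genes with centring and quantile normalization, and germline and pluripotency genes with the latter.

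Counts of called probe sets moved with the settings, and the cause was not tested unless stated. With the intensity trend they were 98 (null set, 0 before), 2052 (wild-type pair, 623 before), 46 (averaged, 0 before) and 738 (difference, 95 before). The filter at the median of signal gave 19, 1528, 9 and 423, fewer and brighter probe sets being tested, and the filter at the lower quartile 1295 in the wild-type pair and 343 for the difference. Quantile normalization gave 1 in the null set, 8 averaged and 207 for the difference, and median centring 974 in the wild-type pair and 228 for the difference. The split of higher and lower calls in the wild-type pair, 398 and 225, became 966 and 1086 with the trend, 664 and 864 above the median, and 562 and 412 after centring. An adjusted p under 0.1 gave 1265 and 267, a log2 difference over 1 gave 231 in the wild-type pair, and 1 probe set per gene gave 154 for the difference. With 4 times the variance for the wild-type arrays both counts were 0 (lowest adjusted p of 0.080 and 0.13). Leaving out 1 array gave 0 to 13 calls in the null set, 340 to 1238 in the wild-type pair, 0 to 0 averaged and 44 to 245 for the difference. A lone array left in a group was then assumed to vary like the others.

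The correlation between backgrounds was 0.40 above the median of signal and 0.12 to 0.31 without 1 array. Lists called, 11 in the null set and 11 averaged, became 0 and 0 with an estimated correlation, and 8 to 16 and 11 to 14 without 1 array. With the replicate number as a block, where same-numbered arrays did not deviate together (r = 0.03 over 2 pairs), 0 probe sets and 11 lists were called, so the block changed neither count in the null set, where alone it was run. Low signal limits the dim probe sets, which no detection value separates from background.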

Other observations

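In the wild-type pair the developmental transcription factors outside the Hox clusters did not move together (median 0.03, 60 of 105 positive), but single members differed widely. Adjusted over the list alone and with the borrowed spread, 10 were higher and 10 lower. The limb and skull factor Msx2 was 1.96 higher, the neural tube factor Zic2 1.85, the skeletal factor Dlx5 1.26 and Gata6 0.91 on the Ezh2-null array, while Tbx20 was lower (log2 difference -3.11). In the Ink4a/Arf-null set Msx2 differed by 0.23 and Zic2 by -0.00 (0.01 after median centring or quantile normalization).

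Neural genes went both ways in the wild-type pair (median 0.00, or -0.02 after median centring or quantile normalization). Fabp7, a glial fatty acid binding protein, was at 2.27, whereas the neuronal genes Stmn2 (-1.96), Gria1 (-1.20) and Mtap2 (-1.11) were lower. Imprinted genes were as mixed there (18 of 34 positive): the growth factor Igf2 was at 1.53 and Dcn at 1.46, and Nnat at -0.90. Secreted factors, too, held both the collagenase Mmp13 (1.43) and the urokinase Plau (-1.06). By cluster, the median Hox difference in the wild-type pair was 1.02 for HoxC, 0.53 for HoxA, 0.36 for HoxD and 0.34 for HoxB genes.

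The p53 target Psrc1 was at 0.68 in the null set and 0.60 in the wild-type pair, and Shcbp1, at -0.52 and -0.50, was likewise nearly equal in both.

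Probe sets of a gene could differ, and 3 such genes were chosen after their values were seen. The channel-like gene Ano3 had a dimmer probe set with a null set difference of 1.30 (SE 0.11, limma adjusted p = 0.26) and 1.69 in the wild-type pair, against 0.46 and 0.90 for its brighter one. A dim probe set of the chromatin protein Hmgb2 was at -3.05 in the wild-type pair, where the brightest was at -0.53, and 1 of 9 probe sets of the ribosomal protein gene Rpl13 was at -3.01 where the brightest was at -0.11. The dim probe sets of Hmgb2 and Rpl13 read below the 10th percentile of signal on the wild-type Ezh2-null array, and that of Ano3 on both Ink4a/Arf-null fx/fx arrays, so the size of these differences is uncertain.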
